A study of Rattus norvegicus with 12 samples.

How the data were processed

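Total RNA from gastric mucosa of 12 libraries with RNA integrity numbers above 7.0 was made into small RNA libraries with a QIAseq kit and sequenced on an Illumina instrument, per the labels' protocols. Such kits add molecular identifiers, and whether the counts are of reads or of molecules is not given in the sources used here. Bowtie and DESeq are named, without version, per the submitters' processing notes. The genome build and the counting rule are not given in the sources used here. The authors deposited 2 tables, one of normal and model libraries and one of model and XLHZ libraries, each with raw counts per mature miRNA, per the file headers and the whole-number values. The deposited CPM columns equal each count divided by its column total, with a largest difference of 5.0e-05, and were used for that check only. miRNAs are named as in the files. Near-identical family members can share reads, so values of single let-7, miR-17-92, miR-34 or miR-200 members are uncertain to that extent. No coordinates are given, because the files name no build.

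The tables held 639 and 632 miRNAs, of which 622 were in both. The model counts were identical in both tables for 621 of these. The exception was miR-20b-3p, with 5, 2, 0 and 0 counts in model libraries 1 to 4 in one table and 251, 152, 1003 and 254 in the other. It was left out wherever the tables were joined. The design had set identical model columns as the condition for joining the tables, and the join was made with this exception. The 17 and 10 miRNAs present in one table alone had at most 3 counts there and were taken as 0 in the other. Groups and replicate numbers came from the sample titles, and columns were matched to samples by their labelled descriptions. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom of 185 or more).

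Each comparison was fitted on its own 8 libraries with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors, filterByExpr with a minimum count of 10) in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all miRNAs tested, at a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. Levels are CPM scaled by TMM over all 12 libraries. The tests and designs, the first set of alternatives, 23 lists of miRNAs and the rule for named miRNAs were fixed before the data were examined. Named miRNAs are up to 12 in each direction with the largest fold change among those that passed with a mean above 10 CPM, filled to 20 by smallest unadjusted p. Up to 4 of the most abundant members of each list were added, with members that passed, 5 opposite-direction miRNAs by smallest larger p, and the 5 most abundant miRNAs. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 (limma 3.58.1), with camera at an estimated correlation and with fry, each adjusted over the 19 lists of a comparison.

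Lists covered epithelium (miR-200 family, intestinal-type, gastric and endocrine, squamous), muscle (smooth, skeletal and cardiac), leukocytes, erythroid cells, endothelium, fibroblasts, nerves, liver and pancreas. Others covered the miR-29, miR-17-92, miR-34/449, let-7, miR-221/222 and miR-196/135 families, hypoxia, the imprinted Dlk1-Dio3 cluster, and miRNAs often reported higher or lower in gastric cancer. The smooth muscle score is the mean log2 CPM of the arms of miR-143 and miR-145.

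Alternatives were other scalings (RLE, upper quartile, library totals), no count filter, at least 50 counts in 4 libraries, DESeq2 1.42.0, robust quasi-likelihood, limma-trend, all 12 libraries in 1 fit, the replicate number as a block, each library left out in turn, library sizes without the 5 most abundant miRNAs, and an unadjusted p with a 2-fold change. Chosen after seeing the data were leaving out model libraries 2 and 3, the smooth muscle score as a covariate, and keeping or leaving out miR-20b-3p. The procedure was tested on simulated counts with known changes. In the model against normal comparison it recovered 50% of 2-fold and 95.8% of 4-fold changes among 391 simulated miRNAs. In the formula against model comparison it recovered 64% and 91.8% among 394, and in the formula against normal comparison 89.8% and 97.9% among 395. Many miRNAs were changed at once there: 199, 197 and 198 were unchanged, and 131, 136 and 171 passed. Such numbers of changes loosen the adjusted threshold. These shares therefore do not give the recovery in the real comparisons, where few miRNAs passed. Among the unchanged miRNAs 2, 1 and 6 passed. In a further simulation the miR-17-92 list alone was shifted 2-fold. Camera with the preset correlation called that list in each comparison, and also 3, 1 and 1 other lists. Some miR-17-92 members also belong to the list often reported higher in gastric cancer. Each miRNA was drawn independently here, with 1 draw per comparison. The simulation therefore does not show how often camera calls unchanged lists whose members move together. The median standard error of a log2 fold change was 0.27, 0.26 and 0.20 in these comparisons.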

Results

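Small RNA libraries were sequenced from rat gastric mucosa in 3 groups of 4 libraries. The normal group had no MNNG exposure. The model group carried chronic atrophic gastritis, a loss of gastric glands that can precede gastric cancer. It was induced over 24 weeks with N-methyl-N'-nitro-N-nitrosoguanidine (MNNG), an alkylating mutagen, at 180 µg/ml in the drinking water, with 2% sodium salicylate by gavage and alternation of 2 days of feeding with 1 day of fasting. The third group, called XLHZ here, had the same exposure and 60 days of Xianglianhuazhuo formula, a herbal preparation. The libraries held 9095260 to 11556061 counts of mature miRNAs each. No label states that the libraries of a group came from separate rats, so p-values measure the spread between libraries. The most abundant miRNA was miR-143-3p, a smooth muscle miRNA, with 157632 ± 39485 CPM (counts scaled to a common library total) in normal mucosa (mean ± SD, n = 4 here and throughout). It was followed by miR-26a-5p, let-7f-5p, let-7a-5p and let-7c-5p, at 57056 ± 2794, 56960.3 ± 2240.2, 50425 ± 1233 and 45834 ± 1543 CPM. Epithelial miR-200a-3p stood at 26251 ± 2029.9 CPM and endothelial miR-126a-3p at 19412 ± 543 CPM. Against normal mucosa, the median miRNA had a log2 fold change of -0.0072 in the model libraries with TMM factors, which set most fold changes near 0. That median was -0.12 on library totals and 0.046 with upper-quartile factors, so it reflects the scaling.

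The first comparison asked which miRNAs differed between atrophic and normal mucosa. Each miRNA hairpin can give mature miRNAs from both arms, and 1 arm usually dominates. A minor arm was the single miRNA that passed in edgeR. The minor arm miR-20a-3p, from the miR-17-92 cluster that acts in cell proliferation, rose from 0.632 ± 0.133 CPM in normal mucosa to 53.3 ± 60.2 CPM in the model. Its log2 fold change was 6.38 (SE 0.82, adjusted p = 0.00773, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and all 4 model libraries lay above all 4 normal libraries. Without model library 3, which was highest, the log2 fold change was 5.21 (adjusted p = 8.50e-06). The other arm of the same hairpin, miR-20a-5p, stood at 1641 ± 170.1 CPM in normal and 1736 ± 605 CPM in model mucosa. miR-20a-3p was the 1 miRNA of 403 tested that passed, and none passed with a lower level. At an unadjusted p under 0.05 there were 17 higher and 12 lower miRNAs, with 20.15 expected by chance. With counts scaled to the library totals alone these were 14 and 19, and with upper-quartile factors 24 and 8. limma-trend called 1 higher and 0 lower, and DESeq2 called 5 higher and 2 lower. The related arm miR-20b-3p had model counts that differed between the deposited tables and is not compared here. The labels give no processing batch, so a batch that follows the groups could not be separated from exposure.

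The miRNAs next in order did not pass. miR-34b-3p, a p53 target that is abundant in ciliated cells, had 6.91 ± 1.64 CPM in normal and 1.05 ± 0.634 CPM in model libraries (log2 fold change -2.75, SE 0.49, adjusted p = 0.0511). It passed with library totals or upper-quartile factors, with no count filter, with at least 50 counts in 4 libraries, with library sizes without the 5 most abundant miRNAs, with DESeq2 and in 1 fit of all 12 libraries. It also passed without model library 4 (adjusted p = 0.00590). miR-551b-3p went from 0.798 ± 0.524 to 58.4 ± 79.4 CPM (adjusted p = 0.166). It passed with DESeq2, in 1 fit of all 12 libraries (adjusted p = 0.0213) and without model library 4 (adjusted p = 0.00590), which held 7 counts of it against 272 to 1574 in the other model libraries. miR-320-3p measured 171 ± 52.1 CPM in normal and 85.3 ± 17 CPM in model mucosa, and miR-204-5p measured 235 ± 18.1 and 614 ± 367 CPM (adjusted p = 0.331 for both). DESeq2 called both, with adjusted p of 0.0388 and 0.0239, and also miR-139-5p (0.0388) and miR-344a-3p (0.0140). Positive log2 fold changes that did not pass in edgeR were those of miR-139-5p (1.11), miR-344a-3p (2.96), miR-124-3p (1.17), miR-338-3p (0.73), miR-133a-5p (1.07), miR-483-3p (1.22), miR-380-3p (0.88), miR-376b-3p (0.65) and miR-9a-3p (0.70). Negative ones that did not pass were miR-339-3p (-0.63), miR-34c-3p (-1.59), miR-155-5p (-0.50), miR-500-3p (-0.64) and miR-664-2-5p (-0.96). miR-375-3p, a miRNA of gastric and endocrine epithelium, had 16832 ± 2867 CPM in normal and 10704 ± 3849 CPM in model mucosa (log2 fold change -0.67, adjusted p = 0.605).

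**Figure D1:**
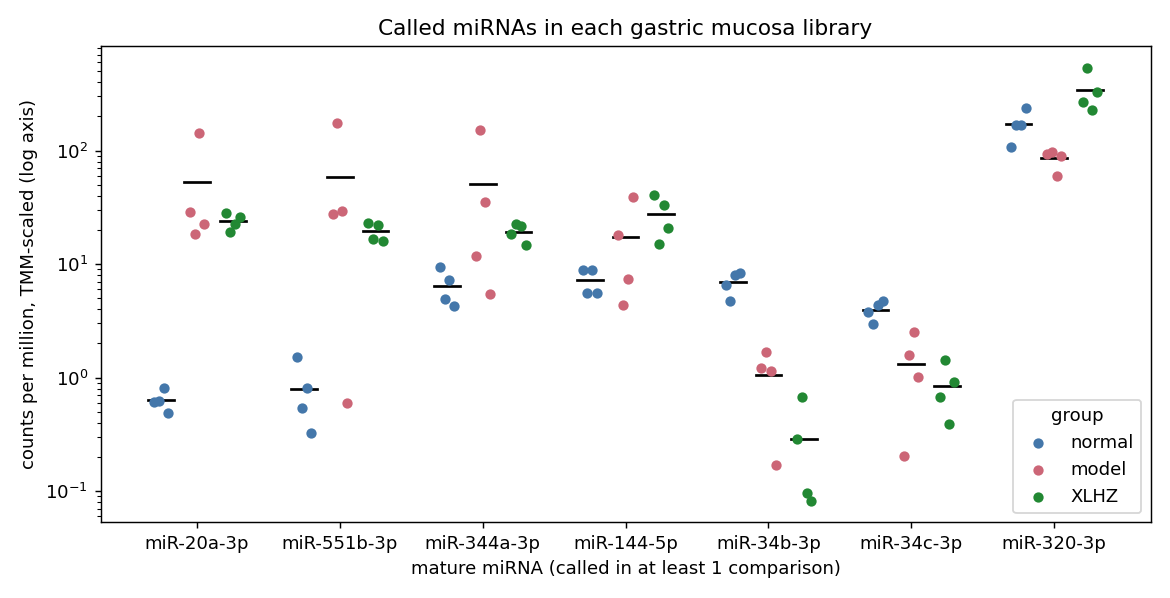
Each point is 1 library and each black bar the mean of 4 libraries, in CPM on a log axis, for the 7 miRNAs that passed in at least 1 comparison. The 4 normal libraries lie below all MNNG-exposed libraries for miR-20a-3p, with group means of 0.632, 53.3 and 24.0 in normal, model and XLHZ mucosa.

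Lists of muscle and nerve miRNAs passed as higher in the model with a preset correlation within lists, and none held with an estimated one. The adjusted p with an estimated correlation was 0.672 for smooth muscle, skeletal muscle, nerves and the gastric cancer list below, and 0.83 for the Dlk1-Dio3 cluster. All 4 tested arms of miR-143 and miR-145, the smooth muscle list, were higher, with a median log2 fold change of 0.62 (camera adjusted p = 0.0173). miR-143-3p measured 243545 ± 104079 CPM and miR-145-5p 34865 ± 15799 CPM in model libraries, the latter against 22399 ± 4401 in normal ones. In the skeletal and cardiac muscle list 6 of 7 members were higher (median 0.90, adjusted p = 0.0145), among them miR-1b at 7442 ± 1638 and 13957 ± 7652 CPM. In the list of neurons and enteric nerves 7 of 8 were higher (median 0.64, adjusted p = 0.00636), with miR-9a-5p at 316 ± 68.9 and 487 ± 184 CPM. The imprinted Dlk1-Dio3 cluster had a median of 0.15 over 44 members (adjusted p = 0.0348). miRNAs often reported lower in gastric cancer had a median of 0.25 over 40 members (adjusted p = 0.0348). Of these, 11 also belong to the muscle and nerve lists, and their median was 0.67 against 0.021 for the others. No member of these 5 lists passed over all miRNAs tested. Adjusted over the list alone, 1 did, the lower miR-34b-3p. In 1 fit of all 12 libraries 4 of the 5 calls ended (adjusted p of 0.0617 for smooth muscle, skeletal muscle and the Dlk1-Dio3 cluster, and 0.0638 for the gastric cancer list). With no count filter the calls of the Dlk1-Dio3 cluster (0.103) and the gastric cancer list (0.0684) ended. That of the Dlk1-Dio3 cluster also ended with at least 50 counts in 4 libraries (0.0809) and with the replicate number as a block (0.0582). With the smooth muscle score as a covariate, chosen after seeing the data, the medians were 0.10 for skeletal muscle, 0.15 for nerves, -0.042 for the Dlk1-Dio3 cluster and 0.0067 for the gastric cancer list, and these 4 calls ended. The score is the mean of the 4 smooth muscle arms, so that list's own median is near 0 there by construction, and the gastric cancer list holds the same 4 arms. The share of all counts taken by miR-143-3p was 29.2% and 25.1% in model libraries 2 and 3, 18.8% and 14.1% in the other two, and 16.0 ± 3.14% in normal mucosa. Without model libraries 2 and 3, a setting chosen after seeing the data, the medians were 0.012 for smooth muscle, 0.014 for skeletal muscle, 0.14 for nerves, 0.11 for the Dlk1-Dio3 cluster and 0.034 for the gastric cancer list, and none of the 5 passed. Leaving out model library 2 alone ended all 5 calls (adjusted p of 0.120 for skeletal muscle and nerves, 0.210 for smooth muscle, 0.827 for the Dlk1-Dio3 cluster and 0.253 for the gastric cancer list). The medians were then 0.32 for nerves, 0.39 for smooth muscle, 0.70 for skeletal muscle, -0.063 for the Dlk1-Dio3 cluster and 0.18 for the gastric cancer list. Leaving out model library 3 ended those of skeletal muscle, smooth muscle and the gastric cancer list (0.196, 0.137 and 0.246). That of smooth muscle also ended without normal library 4 (0.0605), that of the Dlk1-Dio3 cluster without normal library 3 or 4 or model library 4 (0.182, 0.813 and 0.261, with a median of 0.036 without normal library 4), and that of the gastric cancer list without normal library 1, 3 or 4 (0.0745, 0.0980 and 0.120).

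**Figure D2:**
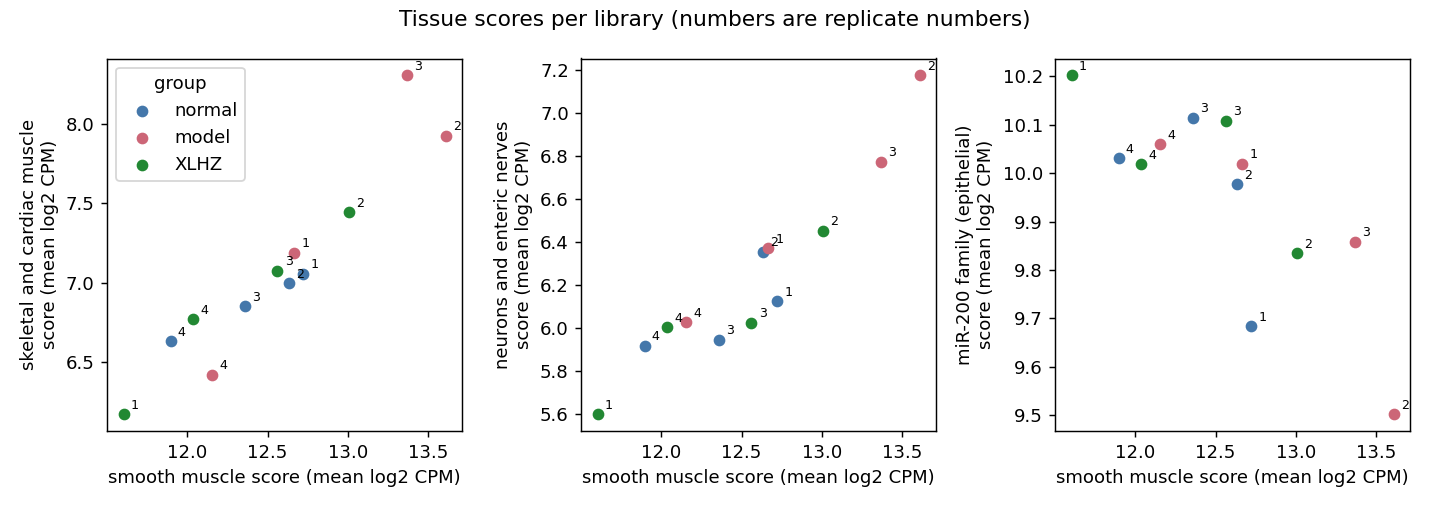
Each point is 1 library, with its replicate number, and each axis a list score, the mean log2 CPM of the list's members; the smooth muscle score is on the horizontal axis of each panel. Over the 12 libraries Pearson's r was 0.94 for skeletal and cardiac muscle, 0.94 for nerves and -0.80 for the miR-200 family.

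No epithelial list passed in the edgeR fit with TMM factors, all 8 libraries and no block or covariate. The 9 members of the miR-200 family, which maintains epithelial identity, had a median log2 fold change of -0.029 in the model, whose sign turned with upper-quartile factors (adjusted p = 0.595). Intestinal-type miR-192, miR-194 and miR-215 had a median of 0.22 (adjusted p = 0.595), with miR-192-5p at 5759 ± 1221 and 6955 ± 3494 CPM. The gastric and endocrine epithelium list had a median of -0.26 and a mean of 0.033, which differ in sign, and its set test pointed down (adjusted p = 0.597). Adjusted over the list alone, 1 of its members passed, the higher miR-204-5p. Squamous epithelial miRNAs such as miR-205 and miR-203a-3p had a median of -0.45, with 5 of 6 lower (adjusted p = 0.0554). With an estimated correlation the adjusted p was 0.672. Normal library 1 stood apart from the other 3 normal libraries for miR-205 (6670.1 against 3426 to 3771 CPM), miR-203a-3p (3225 against 1059 to 1353) and miR-203b-3p (19 against 7.46 to 8.90), and without it the list's median was -0.29 (adjusted p = 0.258). This list passed with upper-quartile factors (0.0480), with the replicate number as a block (0.0424), with the smooth muscle score as a covariate (0.0256) and without model libraries 2 and 3 (0.0413). It also passed without model library 3 (0.0232) or normal library 2, 3 or 4 (0.0469, 0.0459 and 0.0256). Leukocyte miRNAs had a median of -0.077 over 15 members (adjusted p = 0.427, and 0.0251 with a median of -0.22 without model library 3). The adjusted p of the leukocyte list with an estimated correlation was 0.83. Fibroblast miRNAs had a median of 0.038, which turned negative on library totals (adjusted p = 0.597). On library totals alone the median of all miRNAs moved to -0.12.

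The second comparison asked which miRNAs differed between MNNG-exposed mucosa with and without the formula. A single miRNA passed, miR-320-3p, which matures without the usual Drosha step. It was 85.3 ± 17 CPM in the model and 340.5 ± 138 CPM with the formula, a log2 fold change of 2.00 (SE 0.31, adjusted p = 0.0371, edgeR). All 4 XLHZ libraries lay above all 4 model libraries. It was the 1 miRNA of 402 that rose, and 0 fell. At an unadjusted p under 0.05 there were 4 higher and 13 lower miRNAs, against 20.1 expected by chance (8 and 9 on library totals). DESeq2 and limma-trend also called 1 higher and 0 lower. The call ended without any 1 of the model libraries 1, 2, 3 or 4 or of the XLHZ libraries 1 or 4, with adjusted p of 0.153, 0.162, 0.121, 0.136, 0.0658 and 0.123 in that order. In each of these fits the log2 fold change stayed between 1.83 and 2.08. With the smooth muscle score as a covariate it was 2.11 (adjusted p = 0.0595), and without model libraries 2 and 3 it was 1.86 (adjusted p = 0.450).

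The other 19 miRNAs lowest in p all had an adjusted p of 0.729 and did not pass. miR-144-3p, an erythroid miRNA, had 8.59 ± 4.04 CPM in the model and 20.3 ± 6.28 CPM with the formula. miR-338-3p had 429 ± 113 and 266 ± 68.4 CPM, and the neuronal miR-9a-5p had 487 ± 184 and 279 ± 72.3 CPM. Positive log2 fold changes were those of miR-211-5p (0.95) and miR-30b-5p (0.36). Negative ones were those of let-7e-3p (-0.56), miR-708-3p (-1.0), miR-708-5p (-0.96), miR-483-3p (-1.24), miR-547-3p (-0.82), miR-133a-5p (-1.11), miR-100-5p (-0.84), miR-323-3p (-0.88), miR-9a-3p (-0.74), miR-218a-5p (-0.82), miR-204-5p (-0.93), miR-195-5p (-0.37), miR-374-5p (-0.39) and miR-193a-3p (-0.54).

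Lists of muscle and nerve miRNAs passed as lower with the formula with a preset correlation, and none held with an estimated one. The adjusted p with an estimated correlation was 0.564 for each of the 5 lists that follow. All 4 smooth muscle arms were lower (median log2 fold change -0.67, camera adjusted p = 0.00539), with miR-145-5p at 21841 ± 7911 CPM. In the skeletal and cardiac muscle list 6 of 7 were lower (median -0.90, adjusted p = 0.00777), and in the nerve list 7 of 8 (median -0.77, adjusted p = 0.000711). Of the miRNAs often reported lower in gastric cancer, 28 of 38 were lower (median -0.33, adjusted p = 0.000711). The 11 shared with the muscle and nerve lists had a median of -0.82 and the others one of -0.14. All 4 erythroid members, which include miR-451-5p at 16.5 ± 10.0 and 27.8 ± 8.54 CPM, were higher (median 0.69, adjusted p = 0.00344). No member of these 5 lists passed over all miRNAs, and 1, miR-144-3p, passed adjusted over the list alone. Without model libraries 2 and 3, which carry the highest miR-143-3p shares, none passed: the medians were -0.067 for smooth muscle, 0.026 for skeletal muscle, -0.21 for nerves, -0.067 for the gastric cancer list and 0.078 for the erythroid list. With the smooth muscle score as a covariate, which fixes the smooth muscle list by construction, the other 4 calls ended too. The medians were -0.015 for skeletal muscle, -0.21 for nerves, -0.064 for the gastric cancer list and 0.20 for the erythroid list (adjusted p of 0.888, 0.319, 0.646 and 0.422). Leaving out model library 2 alone ended the calls of skeletal muscle, smooth muscle and the erythroid list (adjusted p of 0.0610, 0.0610 and 0.0514, with medians of -0.69, -0.42 and 0.41), and the skeletal muscle call also ended without model library 3 or XLHZ library 1 (0.0965 and 0.0587). The miR-143-3p share in XLHZ mucosa was 15.7 ± 5.93%. The other lists did not pass with all 8 libraries in edgeR. The miR-221 and miR-222 list passed as higher with limma-trend (0.0497) and in 1 fit of all 12 libraries (0.0360). The Dlk1-Dio3 cluster passed as higher without model library 2 (0.0285, median 0.18) and as lower without model library 3 (0.0196, median -0.22). Without model library 3 the intestinal-type list (0.0316, median 0.20) and the list often reported higher in gastric cancer (0.0384, median 0.083) passed as higher. With an estimated correlation and all 8 libraries the adjusted p was 0.997 for the Dlk1-Dio3 cluster, the intestinal-type list and the list often reported higher in gastric cancer. Among the others, the miR-200 family had a median of 0.14 (adjusted p = 0.250) and the gastric and endocrine epithelium list one of 0.25 (adjusted p = 0.497). On library totals alone the median of all miRNAs moved to 0.17.

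**Figure D3:**
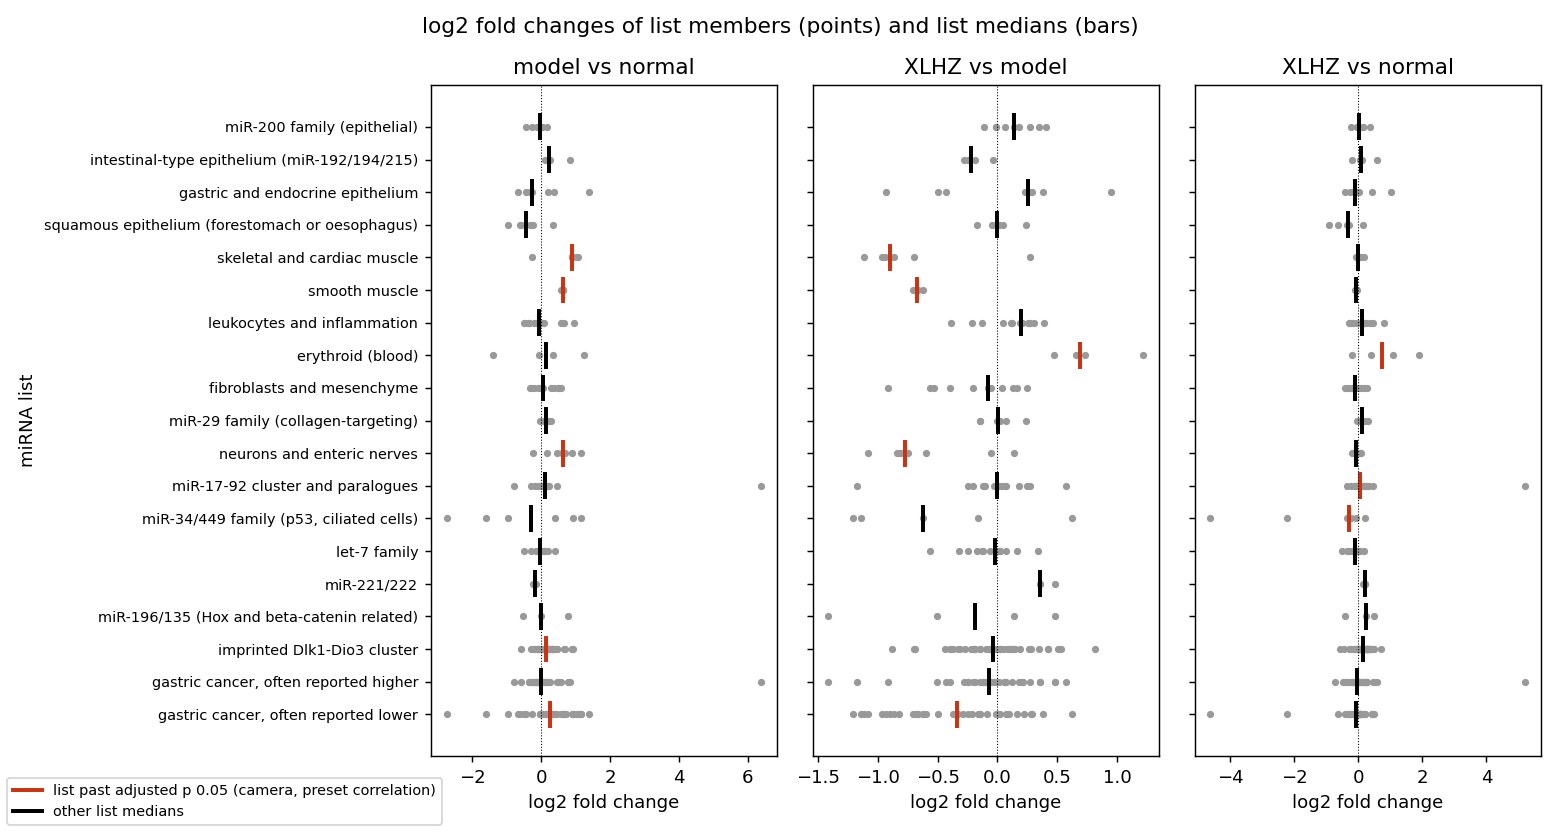
Each point is the log2 fold change of 1 list member and each bar the median of its list, for 19 lists in the 3 comparisons; red bars mark lists past an adjusted p of 0.05 in camera with a preset correlation. The smooth muscle median was 0.62 in the model against normal mucosa, -0.67 with the formula against the model, and -0.058 with the formula against normal mucosa.

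The third comparison asked how far formula-treated, MNNG-exposed mucosa lay from normal mucosa. Single arms of a few hairpins differed, among them the p53-regulated miR-34b and miR-34c, while muscle and nerve miRNAs as groups did not pass. In edgeR 6 of 401 miRNAs passed, 4 higher and 2 lower. miR-20a-3p rose to 24.0 ± 4.11 CPM (log2 fold change 5.20, SE 0.24, adjusted p = 1.24e-06), and miR-551b-3p rose to 19.4 ± 3.60 CPM (4.59, SE 0.37, adjusted p = 0.000108). The erythroid miR-144-5p rose from 7.23 ± 1.90 to 27.5 ± 11.6 CPM (1.89, SE 0.32), and miR-344a-3p rose from 6.45 ± 2.32 to 19.3 ± 3.62 CPM (1.56, SE 0.25), each with an adjusted p of 0.0136. miR-34b-3p fell to 0.285 ± 0.275 CPM (-4.61, SE 0.50, adjusted p = 0.000770). miR-34c-3p fell from 3.95 ± 0.779 to 0.851 ± 0.447 CPM (-2.22, SE 0.37, adjusted p = 0.0136). Its partner arm miR-34c-5p measured 105 ± 13.2 and 104 ± 11.4 CPM. At an unadjusted p under 0.05 there were 21 higher and 14 lower miRNAs, with 20.05 expected by chance. DESeq2 called 4 higher and 3 lower, and limma-trend called 4 and 2. In 1 fit of all 12 libraries miR-20a-3p and miR-34b-3p passed and the others did not (adjusted p of 0.161 for miR-551b-3p, 0.350 for miR-144-5p, 0.891 for miR-344a-3p and 0.143 for miR-34c-3p). Their log2 fold changes there were 4.61, 1.93, 1.59 and -2.20. The call of miR-144-5p ended without normal library 2 or 4 or XLHZ library 3 (adjusted p of 0.0654, 0.0605 and 0.0655), and that of miR-344a-3p without normal library 2 or XLHZ library 3 (0.0578 and 0.0655). That of miR-34c-3p ended without normal library 4 or XLHZ library 1 (0.050 and 0.0571) and with the replicate number as a block (0.139). Without XLHZ library 2 the log2 fold change of miR-34b-3p was -5.46.

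miRNAs that followed in p without passing included miR-193a-5p, with 42.4 ± 5.11 CPM in normal and 27.6 ± 2.98 CPM in XLHZ mucosa (adjusted p = 0.183), which DESeq2 called. Further positive log2 fold changes that did not pass were those of miR-451-5p (1.07), miR-320-3p (0.97), miR-215 (0.59), miR-106b-5p (0.45), miR-450a-5p (0.40), miR-30e-3p (0.28) and miR-30e-5p (0.27). Negative ones were those of let-7e-3p (-0.51), miR-365-3p (-0.55), let-7b-5p (-0.28), let-7c-5p (-0.15), miR-181b-5p (-0.48) and miR-203b-3p (-0.92). Of the lists, the miR-34 and miR-449 family was lower in 5 of 6 members (median -0.29, camera adjusted p = 0.00111, and 0.0107 in fry), and 2 members passed both over all miRNAs and adjusted over the list alone. These were miR-34b-3p (-4.61) and miR-34c-3p (-2.22), which pull the list's mean to -1.21. Their partner arms changed by -0.35 (SE 0.64) and -0.056 (SE 0.13). The list was not tested without these 2 arms, so the call does not show a fall of the whole family. The erythroid list was higher in 3 of 4 members (median 0.74, adjusted p = 0.0189), with 1 member past the threshold over all miRNAs and 2 adjusted over the list alone. The miR-17-92 list passed (adjusted p = 0.0360) with a median of 0.05, 8 members higher and 8 lower, and 1 member, miR-20a-3p, past the threshold over all miRNAs and over the list alone. None of these 3 calls held with an estimated correlation (adjusted p = 0.184, 0.651 and 0.920 with an estimated correlation). The erythroid call ended without normal library 2 or XLHZ library 1 (0.0791 and 0.0601), and the miR-17-92 call without normal library 1 or 2 or XLHZ library 4 (0.0892, 0.0791 and 0.265, with medians of 0.13, 0.041 and -0.0083). The erythroid medians were then 0.57 and 0.47. The miR-17-92 call also ended with limma-trend (0.132), with the replicate number as a block (0.138), in 1 fit of all 12 libraries (0.0565) and with the smooth muscle score (0.0574). The miR-34 and miR-449 family did not pass with limma-trend (0.0595, median -0.097). The let-7 family passed in fry (adjusted p = 0.0458) and not in camera (0.169), except with limma-trend (0.0126). Its adjusted p with an estimated correlation was 0.651. In fry's test for change in either direction the lists often reported higher (adjusted p = 6.7e-08) and lower (6.1e-05) in gastric cancer passed. So did miR-17-92 (3.6e-07), the miR-34 and miR-449 family (0.00067) and let-7 (0.0080). All of these but let-7 hold at least 1 arm that passed over all miRNAs. Smooth muscle and nerve lists had medians of -0.058 and -0.077 (adjusted p = 0.795 for both). The Dlk1-Dio3 cluster, with a median of 0.16 (adjusted p = 0.194), passed as higher without normal library 1 (0.00246, median 0.34) or XLHZ library 4 (0.00678, median 0.30) and with the replicate number as a block (0.0193). The list often reported lower in gastric cancer had a median of -0.053 (adjusted p = 0.205), whose sign turned with upper-quartile factors, and passed as lower without XLHZ library 2 (0.0113, median -0.27). With an estimated correlation and all 8 libraries the adjusted p was 0.990 for both.

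The formula was studied for its effect on the progression from atrophic gastritis to gastric cancer, so the first comparisons were set side by side. No miRNA passed in both with opposite direction. DESeq2 gave 1, miR-320-3p. With an unadjusted p under 0.05 in both, 7 miRNAs differed in opposite directions and 0 in the same direction. Simulated unchanged groups that shared the 4 model libraries gave 4.12 ± 1.89 in opposite directions (100 simulations), and regroupings of the real libraries gave 4.59 ± 6.98, with 18 of 100 at 7 or more. In the same direction they averaged 0.03 and 0.14, so a count of 0 there follows from the shared libraries. With the model libraries split 2 and 2, the averages were 3.83 in opposite directions and 2.5 in the same direction. miR-320-3p had log2 fold changes of -1.02 in the model and 2.00 with the formula. miR-338-3p had 0.73 and -0.70, miR-483-3p had 1.22 and -1.24, the muscle miRNA miR-133a-5p had 1.07 and -1.11, and miR-323-3p had 0.93 and -0.88. Across 394 miRNAs, which are not independent replicates, Pearson's correlation of the 2 sets of fold changes was -0.64, as was Spearman's. Simulated groups without any effect gave -0.51 ± 0.056, because the model libraries enter both comparisons. Regroupings of the real libraries gave -0.49 ± 0.18, and 24 of 100 were at or below the observed value. The covariance was -0.16 against a simulated -0.060, a difference of -0.10, and 3 of 100 regroupings had a covariance at or below the observed one. The simulation gave each miRNA 1 dispersion for all groups, and regrouping mixes the model libraries with the others. Neither keeps a larger spread of the model group, which alone would lower the covariance. The median standard error was 0.27 and 0.26 in the comparisons with model libraries and 0.20 without them. The covariance therefore cannot decide on a reversal. With separate model libraries in each comparison, 2 and 2, the correlation averaged -0.12 over 6 splits, between -0.25 and -0.012. The covariance averaged -0.039 over these splits, between -0.085 and -0.0043. With the smooth muscle score as a covariate, chosen after seeing the data, the correlation was -0.37.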

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

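Leaving out model libraries 2 and 3 and the smooth muscle covariate were settings chosen after seeing the data, with bounds written before their results. The tests of the single miRNAs, of miR-20b-3p, of epithelial share, of the score over all 4 libraries and of the depth of model library 3 were chosen only after their results were seen. The others were set before.

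A library was listed here when it stood apart from the other 3 of its group by Dixon's test. This happened for 24 of the 339 combinations of named miRNA and group, and chance gives about 1 in 20, or 16.95. Values are CPM, against the range of the other 3 libraries. Model library 3 held 7 of them. It was high for the inflammation-related miR-21-5p (90254 against 33589 to 38166) and miR-146a-5p (6123 against 1282 to 1398), for the p53 targets miR-34a-5p (2128 against 292 to 517) and miR-34c-5p (637 against 71.3 to 122), for miR-135b-5p (29.8 against 7.70 to 9.57) and for miR-20a-3p (143 against 18.5 to 28.9). It was low for miR-221-5p (6.99 against 12.4 to 13.3). Model library 2 was high for miR-551b-3p (176 against 0.593 to 29.5) and miR-382-5p (102 against 48.5 to 52.9), and model library 4 for miR-499-5p (155 against 108 to 114).

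Normal library 1 held 8. It was high for the squamous miRNAs miR-205 (6670.1 against 3426 to 3771), miR-203a-3p (3225 against 1059 to 1353) and miR-203b-3p (19 against 7.46 to 8.90), and for the pancreatic miR-217-5p (5.90 against 0.566 to 1.26). It was also high for the leukocyte miR-142-3p (3001 against 2106 to 2247) and let-7c-5p (48146 against 44948 to 45126), and low for miR-124-3p (1.93 against 3.14 to 3.29) and miR-193a-5p (34.8 against 44.3 to 45.4). Normal library 4 was high for miR-222-3p (55.1 against 45.9 to 46.8) and low for miR-19b-3p (2004 against 2974 to 3159) and miR-338-3p (166 against 279 to 292). XLHZ library 2 was high for miR-196a-5p (1.63 against 0.191 to 0.412) and low for miR-31a-5p (2943 against 3703 to 3841), and XLHZ library 3 was high for let-7f-5p (62079 against 53027 to 53579).

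Over all 417 miRNAs tested, model library 3 was the one apart in its group for 17, or 4.08%. This is under the bound of 5% set for chance, but that bound holds for a group of 4, so a single library would be expected to hold 1 of 4 parts of it, and chance may not account for all 17. Removing the smooth muscle score left 16. Model library 2 had a higher smooth muscle score than model library 3 (13.61 against 13.37). A miRNA that follows muscle content would thus hardly set model library 3 alone apart, so this count cannot decide on muscle content. The library had 530 miRNAs detected, the fewest of the 12 (539 or more in the others), with a total count inside their range, so fewer detected miRNAs cannot be told apart from a different tissue state. A stronger response of that tissue to MNNG stays open as untested.

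The 6 miRNAs that passed between normal and MNNG-exposed mucosa are single arms. For the 4 with a tested partner arm, the median change of the partner in the direction of the called arm was 0.011 on the log2 scale in formula against normal mucosa. It was 3.42 for the called arms, which were picked for their change. In that comparison this argues against a change in transcription of the whole hairpin, though partner SEs reached 0.78. In the model against normal mucosa miR-20a-5p (0.075) and miR-34b-5p (-0.96) had the sign of their called arms. There miR-34c-5p (1.15) and miR-144-3p (-1.40) had the opposite sign. Of the 6, which had already passed a count filter, 5 had at least 50 counts in each library of the higher group. In the lower group miR-20a-3p, miR-34b-3p, miR-34c-3p and miR-551b-3p had at most 9, 7, 15 and 15 counts in a library. The sizes of these fold changes thus rest on few counts on that side. Of the 6, 0 had model counts that differed between the tables. Processing of the normal libraries apart from the others cannot be told apart from MNNG exposure: 3 of the 6 had a model library inside the normal range, and the other 3, miR-20a-3p, miR-34b-3p and miR-34c-3p, had none. For miR-20b-3p the ratio of its counts to those of miR-20a-3p in the table of model and XLHZ libraries varied by a factor of 1.46 at most (0.729 to 1.06), under a bound of 1.5 set after the ratios were seen. A constant ratio was rejected over the 8 libraries (chi-square p = 1.05e-05) and not without model library 3 (p = 0.731), so reads of miR-20a-3p counted under both names there stay open.

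Muscle and nerve lists passed as higher in the model with a preset correlation, and not with an estimated one (adjusted p = 0.672 for the smooth muscle, skeletal muscle and nerve lists). With the smooth muscle score as a covariate the nerve list's median log2 fold change went from 0.64 to 0.15. A larger share of muscle wall, which carries enteric nerves, in the dissected mucosa would give such a fall. Any other cause that moves both lists together would give it too, since the 2 scores had a Pearson's r of 0.94 over the 12 libraries. The fall cannot tell these causes apart. A lower share of epithelium that raises every other cell type alike stays open, since the smooth muscle minus leukocyte score was higher in the model by 0.63, less than its larger SD of 0.73. Whether the model group shares the shift cannot be told: the difference in smooth muscle score had an exact two-sided permutation p of 0.229 over 70 splits, and 2 of 4 model libraries lay above all normal ones. The test set beforehand, the smooth muscle median without model libraries 2 and 3, gave 0.012, under the bound set for an effect not shared by the group, but these 2 libraries were left out for their high muscle miRNAs, so a fall follows from the choice and the bound was wrong.

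Other splits of the same 8 libraries into 4 and 4 were counted for each comparison. For the model against normal libraries, 2 of 35 splits called as many miRNAs as the real one (1, highest other 1), so chance is not excluded by this count. For the formula against the model it was also 2 of 35 (1, highest other 1). For the formula against normal mucosa the real split called 6 and the highest other 0, so 1 of 35 reached it. This is the smallest share that 35 splits can give, and 3 comparisons were counted without adjustment. Chance is therefore not excluded by this count either.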

How the results depend on the processing

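Settings without model libraries 2 and 3, with the smooth muscle score and with miR-20b-3p kept or left out were chosen after seeing the data. Of 143 comparisons of main results with their alternatives, 116 stayed within 1.5 times of the count or within the spread, and 27 moved. The cause of a move was not tested unless given. The spread is a jackknife SE of 0.20 for the correlation. Counts were compared by size and not by which results were called, and 0 against 0 was taken as staying. The list calls in 1 fit of all 12 libraries were taken as staying with 9, of which 8 were among the 13 reported. Model against normal called 1 miRNA; it called 2 with upper-quartile factors, library totals, at least 50 counts or library sizes without the 5 most abundant, 3 with no filter, 4 with all 12 libraries in 1 fit, 7 with DESeq2 and 12 at an unadjusted p with a 2-fold change. With a library left out it called 1 to 4, the highest without model library 4. Formula against model called 1, and 0 without model libraries 2 and 3 (fewer libraries), 0 with the score (miR-320-3p kept a log2 fold change of 2.11), 5 at an unadjusted p with a 2-fold change, and 0 to 1 with a library left out. Formula against normal called 6, and 2 with all 12 libraries in 1 fit, and 4 to 7 with a library left out, the highest without XLHZ library 2. Opposite-direction calls were 0, but 1 with DESeq2 and 3 at an unadjusted p with a 2-fold change. There were 13 list calls, and 0 with an estimated correlation. With the score there were 6, of which 2 were among the 13 and 4 were others. Without model libraries 2 and 3 there were 7, of which 3 were among the 13, and without model library 2 there were 7, of which 5 were. Without model library 3 there were 16, of which 9 were. The correlation of -0.64 became -0.37 with the score and -0.12 with the model libraries split, where sharing was removed by construction. It lay between -0.71 and -0.50 with a library left out.

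Some list medians or tests turned direction. With the score as a covariate the model against normal median of the Dlk1-Dio3 cluster was -0.042. With a library left out, the Dlk1-Dio3 cluster lay between -0.063 and 0.40 in model against normal and between -0.22 and 0.18 in formula against model, turning without model library 2. In formula against model, the intestinal-type list lay between -0.45 and 0.20 and the list often reported higher in gastric cancer between -0.14 and 0.083, both turning without model library 3. Without model libraries 2 and 3 the model against normal medians were 0.014 for skeletal muscle, 0.012 for smooth muscle and 0.034 for the list often reported lower in gastric cancer, and skeletal muscle had 0.026 in formula against model. Other scalings turned the sign of medians of lists that had not passed. Of 19 lists, RLE, upper-quartile factors and library totals turned 3, 4 and 2 in model against normal, 1, 2 and 7 in formula against model, and 0, 3 and 2 in formula against normal. On library totals in formula against model the Dlk1-Dio3 median went from -0.035 to 0.13, that of fibroblasts from -0.074 to 0.12 and that of let-7 from -0.020 to 0.15. Of the other list results, 935 stayed the same, 66 lost and 32 gained a call and 77 moved. Of single-miRNA results, 6190 stayed the same, 20 lost and 16 gained a call and 499 moved.

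The replicate numbers did not pair the libraries: libraries with the same number correlated between -0.32 and 0.44, and not every library correlated best with its own number. With the replicate number as a block, the counts of calls were 1, 1 and 5, there were 13 list calls and the correlation was -0.48. With this block miR-34c-3p lost its call in formula against normal (adjusted p = 0.139). The 13 list calls were not the same 13 with the block: the Dlk1-Dio3 cluster in model against normal (0.0582) and miR-17-92 in formula against normal (0.138) dropped out, and squamous epithelium in model against normal (0.0424) and the Dlk1-Dio3 cluster in formula against normal (0.0193) came in. Lists were not tested with DESeq2 or without the 5 most abundant miRNAs, and the pseudocount alternative was not run because the values are raw counts. Whether depth limits calls of miRNAs near 10 counts was not tested.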

Other observations

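The score correlations were chosen after the list results were seen. In the model against normal mucosa the camera adjusted p was 0.0554 for the miR-34 and miR-449 family, whose median log2 fold change was -0.28 with 3 of 6 members lower and 2 passing adjusted over the list alone, and 0.736 for the erythroid list. The miR-34 and miR-449 family passed in fry's test for change in either direction (adjusted p = 0.0200). With an estimated correlation its adjusted p was 0.672. In camera with the preset correlation it passed with RLE factors (0.0480), upper-quartile factors (0.0325) and the smooth muscle score (0.0316). It also passed without model library 3 (0.00277, median -0.52), normal library 2 (0.0117, median -0.45) or model libraries 2 and 3 (0.00861, median -0.65). The erythroid list passed with the smooth muscle score (0.0316, median 0.55) and without model libraries 2 and 3 (0.0267, median 0.67). Its adjusted p with an estimated correlation and all 8 libraries was 0.894. The collagen-targeting miR-29 family had a median of 0.15 (adjusted p = 0.320), with miR-29a-3p at 42512 ± 4061 CPM in normal and 41618 ± 934 CPM in model mucosa. The miR-17-92 list had 0.097 (0.320), let-7 -0.026 (0.595), miR-221 and miR-222 -0.19 (0.430), miR-196 and miR-135 -0.0011 (0.934) and miRNAs often reported higher in gastric cancer -0.0048 (0.928), given as medians with adjusted p. Adjusted over the list alone, 1 member, miR-20a-3p, passed in the miR-17-92 list and in the list often reported higher in gastric cancer, as it did over all miRNAs. The signs of the let-7, miR-196 and gastric cancer medians turned with RLE and upper-quartile factors, and that of miR-17-92 on library totals. The miR-17-92 list passed without model library 2 (0.00946, median 0.28), without model libraries 2 and 3 (0.00446, median 0.22) and with the smooth muscle score (0.0256, median 0.19). Its adjusted p with an estimated correlation and all 8 libraries was 0.83. With the formula against the model, miR-221 and miR-222 had a median of 0.36, with all 3 members higher (adjusted p = 0.0575, 0.0360 in 1 fit of all 12 libraries, 0.0497 with limma-trend, and 0.0250 and 0.0406 without XLHZ library 2 or 3), and leukocyte miRNAs one of 0.20, with 12 of 15 higher (0.155, and 0.00135 and 0.0314 without model library 3 or XLHZ library 1). With an estimated correlation and all 8 libraries the adjusted p was 0.564 for miR-221 and miR-222 and 0.646 for leukocyte miRNAs. In the edgeR fits with TMM factors, all 8 libraries and no block or covariate, none of these lists passed in camera in the comparisons given here.

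Lists with fewer than 3 tested members were not tested as sets. Endothelial miR-126a-3p stood at 17907 ± 2439 CPM in model and 19846 ± 2227 CPM in XLHZ mucosa. The liver miRNA miR-122-5p had 6.50 ± 3.99, 36.1 ± 44.2 and 19.9 ± 23.6 CPM in normal, model and XLHZ mucosa. The pancreatic miR-216a-5p had 3.33 ± 2.87, 2.79 ± 1.64 and 2.36 ± 1.60 CPM. Hypoxia-responsive miR-210-3p had 123 ± 21.5, 159 ± 18.6 and 143 ± 21.0 CPM. None of these miRNAs passed in any of the 3 comparisons.

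Scores of 8 other lists were compared with the smooth muscle score over the 12 libraries. Pearson's r was 0.94 for skeletal and cardiac muscle (Spearman's rho 0.94, permutation p 2.0e-05 and 6.0e-05, adjusted p of r 8.0e-05) and 0.94 for nerves (rho 0.94, permutation p 1.0e-05 for both, the smallest these resamples can give, adjusted p 8.0e-05). It was 0.84 for fibroblasts (rho 0.80, permutation p 0.000890 and 0.00334, adjusted p 0.00237) and -0.80 for the miR-200 family (rho -0.80, permutation p 0.00139 and 0.00269, adjusted p 0.00278). Centred within groups, r was 0.93, 0.93, 0.82 and -0.78. Without model library 2 and XLHZ library 1, the farthest from the median score, r was 0.92, 0.90, 0.84 and -0.58. Leukocyte miRNAs had an r of -0.22 (rho -0.091, permutation p 0.488 and 0.782). Without the same libraries it was 0.13. The erythroid r was -0.57 (rho -0.57, permutation p 0.0540 and 0.0564), the endothelial one -0.55 (rho -0.43, permutation p 0.0650 and 0.170) and that of gastric and endocrine epithelium -0.16 (rho -0.36, permutation p 0.621 and 0.256). Adjusted p was 0.558, 0.0865, 0.0867 and 0.621 for these 4 in the order given, and without the 2 farthest libraries the last 3 r were -0.19, -0.37 and -0.0093.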
